A study of Homo sapiens with 6 samples.

How the data were processed

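RNA came from MDA-MB-231 cells, 3 libraries of wild-type cells and 1 library from each of 3 Ki-67 knockout clones. Per the labels' protocols, mRNA was purified with oligo(dT) beads, fragmented and reverse transcribed with random hexamers, and no step that marks the strand is described. Libraries were sequenced with paired reads on a DNBSEQ instrument. Per the submitters' processing notes, FastQC, STAR 2.6.0c and DESeq2 were used with the GRCh38.p13 build. The annotation release is not given in the sources used here.

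The deposited files hold raw read counts per gene, not normalized, in the layout that STAR writes, with 1 file per library. Column 2 holds counts without regard to strand and was used here. Columns 3 and 4 count each strand setting, and column 3 held 49.3% to 50.5% of their sum, as in a library without strand, so reads of overlapping or antisense genes cannot be told apart. A change in the counts of either strand setting can therefore include reads of an overlapping gene. The first 4 rows name no gene (unmapped, multimapping, no feature, ambiguous). They held 18.0% to 20.0% of all reads and were left out of library sizes and tests. Reads that map to several places are not in the gene counts, so genes with near-identical copies, such as histones, ribosomal proteins and HLA genes, are counted only where reads are unique.

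Each file listed 60715 gene identifiers, of which 60401 matched a symbol and a position in GENCODE release 44 after the version was removed. That release is on a later patch of GRCh38 than the files name, and coordinates are given on primary chromosomes.

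Counts in genes were 29095692 to 31091670 per library, so a floor of 3 counts is 0.0965 to 0.103 CPM in 1 library. KO was compared with WT in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM normalization, robust dispersion estimates and the quasi-likelihood F-test, 2-sided, with Benjamini-Hochberg adjustment over 16159 genes and a threshold of 0.05. The standard error is the absolute log2 fold change over the square root of F. CPM values are counts scaled to a library size of 1e6 after TMM scaling. Gene lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a correlation of 0.01 and adjustment over the 30 lists tested of 32 fixed. The same test with an estimated correlation called 0 lists, with 0 lists under an unadjusted p of 0.05. The fry test, which asks whether a list moves on balance one way and does not compare it with other genes, called 18 lists, and its mixed version 30.

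The groups, tests, alternatives, lists and rule for named genes were fixed before the data were examined. The rule took MKI67, then the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among genes that passed the test, had a mean log2 CPM of at least 1 and had KO and WT values apart, and then up to 4 members of each list with the smallest adjusted p under 0.05, or 2 members as values where none passed. Where 5 or fewer members of a list moved one way they may be named beyond this rule, and those were chosen after their values were seen. The blocks of 20 Mb, with at least 20 genes of mean log2 CPM 2 or more, their thresholds and the 8-fold rule for genes that vary within a group were also chosen after the data had been seen.

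Pairs of libraries within a group differed by more than counting noise, so none was counted as a repeat. The chi-square per degree of freedom was 3.21 for WT replicates 2 and 3 and 16.0 to 23.4 for the other pairs. Such values do not show that libraries came from separate cultures. Alternatives covered other normalizations, DESeq2 1.42.0, limma-voom, the filter on low counts, a block on the replicate number, the counts of either strand setting, each library left out in turn, glmTreat, and, chosen after the data had been seen, changes relative to neighbouring genes.

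The edgeR step was tested on counts simulated for 16159 genes from the means and depths of these libraries, with 200 genes changed. With gene-wise dispersions, over 30 draws, 47.4%, 88.3% and 99.0% of the genes changed by 0.5, 1 and 2 on the log2 scale were called, and 8.69% of the calls were false, against a nominal 5% (3.75% to 12.9% in single draws). The test was first run on a single draw, in which 12.1% of the calls were false, above the limit of 12% that had been set for it; the further draws were added after that, with the limit kept for their total. With dispersions taken from the trend instead, 4.69% of the calls were false over 30 draws. With gene-wise dispersions more of the simulated calls were thus false than the nominal share. Only 200 of 16159 genes were changed there, against 9580 called in the data, so that share does not carry over to these calls. Of 100 unchanged lists 1 had a camera p under 0.05. Genes were drawn independently of each other there, so this cannot show how camera behaves where the members of a list are correlated.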

Results

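Poly(A)-selected RNA was sequenced from MDA-MB-231, a human triple-negative breast adenocarcinoma cell line, either unmodified or after knockout of MKI67, the gene of the proliferation marker Ki-67. There were 6 libraries, 3 from wild-type (WT) cells and 1 from each of 3 Ki-67 knockout (KO) clones, which the labels call independent. The comparison asks how the transcriptome of the knockout clones differed from that of the WT line. Counts assigned to genes ranged from 29095692 in WT replicate 2 to 31091670 in WT replicate 1, and the KO libraries held 30768886, 30242716 and 29591950. The 10 most counted genes took 4.72% to 5.09% of the counts of a library. Reads outside annotated features made up 5.16%, 6.32% and 6.67% of the WT libraries and 4.12%, 4.57% and 4.20% of the KO libraries.

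MKI67 (ENSG00000148773.14, chromosome 10, 128096659 to 128126423 on GRCh38, minus strand) fell by 2.81 on the log2 scale in the knockout clones. It stood at 485 ± 92.0 CPM in WT and 69.3 ± 9.84 CPM in KO (SD, n = 3 each). The WT libraries gave 585, 404 and 467 CPM and the KO libraries 61.3, 80.2 and 66.3 CPM, so every library went with its label. The log2 fold change had an SE of 0.145 (edgeR quasi-likelihood adjusted p = 1.13e-07). Measured relative to the other genes of its 20-Mb block, which were also lower in KO, it was -2.17, a comparison added after the data had been seen. Transcript remained in all 3 clones, and per-gene counts do not show where along the gene its reads lay.

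**Figure D1:**
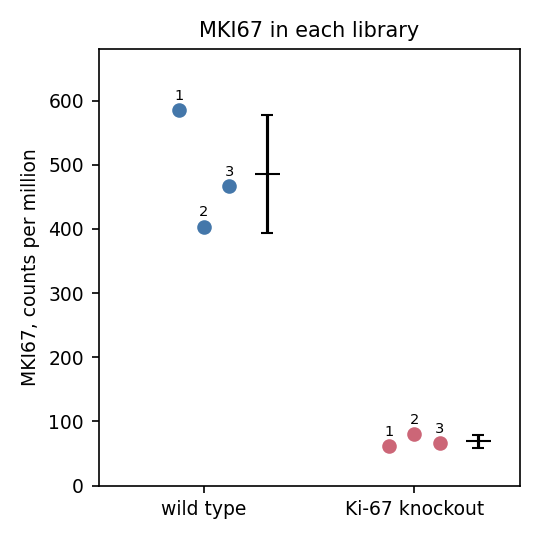
MKI67 in CPM (vertical axis) in the 3 wild-type and 3 Ki-67 knockout libraries; numbered points are replicates, and the bars give the mean ± SD of each group. The highest knockout library, at 80.2 CPM, lies below the lowest wild-type library, at 404 CPM.

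Knockout clones differed from WT cells in more than 50% of the genes tested. Of 16159 genes, 9580 (59.3%) changed at an edgeR adjusted p under 0.05, 4906 of them higher and 4674 lower in KO. Changes of at least 2-fold were found in 3338 genes, 1480 higher and 1858 lower, and changes of at least 16-fold in 56 higher and 130 lower genes. In 10655 of all tested genes (65.9%) the 3 KO values lay on one side of the 3 WT values, against 10% expected by chance for 3 against 3. The first principal component of log2 CPM held 84.1% of the variance and parted the groups, with KO at 60.7 to 63.9 and WT at -69.3 to -52.2. A test against a change of 2-fold, rather than a filter after the test, left 1526 genes. Genotype cannot be separated from other ways in which the clones differ from the WT line, such as clonal selection or a library batch. Nothing in the labels says that the WT libraries came from separate cultures. All 3 clones also shared shifts of neighbouring genes, described below, which leaves open whether they are separate replicates of the knockout. The p-values therefore measure the spread between these libraries only.

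Several genes were detected in KO and nearly absent from WT. PCSK1N, a neuroendocrine proprotein convertase inhibitor, had 0 counts over the WT libraries and 433 over the KO libraries, at least 140-fold higher against a floor of 3 counts over the group. COL4A5, a basement membrane collagen chain, had 0 and 351 counts, at least 114-fold higher. TMEM98 rose from 0.0461 ± 0.0799 to 8.72 ± 1.77 CPM, and RORB, a nuclear receptor, from 0.114 ± 0.0550 to 10.2 ± 1.66 CPM (SD, n = 3). MVB12B (log2 fold change 6.29), ADGRE1 (6.06), RETREG1 (5.61), the organic cation exporter SLC47A1 (5.40), the G protein subunit GNA15 (5.26) and the sphingosine-1-phosphate transporter SPNS2 (5.06) completed the 10 largest increases, with edgeR adjusted p of 7.97e-07 or lower. Relative to its neighbours, which fell, RETREG1 rose by 6.44 on the log2 scale. In the counts of either strand setting SPNS2 rose by 3.75 and 3.59. TMEM98, MVB12B, ADGRE1 and GNA15, with few counts in WT, also moved by more than 1.5-fold under single alternatives, TMEM98 between 6.71 and 11.04, and kept direction and call.

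Other genes were lost from KO. ESM1, an endothelial-type secreted proteoglycan, fell from 128.0 ± 8.67 CPM to 0.0884 ± 0.0522 CPM (SD, n = 3; edgeR adjusted p = 8.61e-12). ASTN1, the homeodomain factor gene NKX6-1 and PABPC4L had 890, 662 and 380 counts over the WT libraries and 0 over the KO libraries, at least 305-fold, 227-fold and 130-fold lower. UGT8, a galactosyltransferase of sphingolipid synthesis, had 3327 counts in WT and 2 in KO, a ratio of 1711 with a 95% counting interval of 473 to 14135. NAP1L5 had 1037 and 2 counts (ratio 533, interval 147 to 4410), and HCLS1 463 and 2 counts (ratio 238, interval 65.5 to 1972). NCKAP1L, a WAVE complex member of blood cells, fell by 8.53 on the log2 scale, SLCO4C1 by 7.99 and the phosphoinositide kinase gene PIK3CG by 7.90. Intervals and floors cover counting error only. The size of the change in SLCO4C1, PIK3CG, HCLS1, NAP1L5 and UGT8, with few counts in KO, depended on the alternative (SLCO4C1 between -10.54 and -6.98), and each kept direction and call in all of them.

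Genes of the cell cycle rose together in the clones. In the list of S phase and DNA replication genes, 21 of 25 measured members rose, RRM1 fell and 3 did not pass the test, with the same counts adjusted over the list alone. POLA1, the catalytic subunit of DNA polymerase alpha, rose from 62.4 ± 3.84 to 181 ± 20.3 CPM, and CCNE1, a cyclin of S phase entry, from 9.03 ± 2.17 to 29.8 ± 3.21 CPM (SD, n = 3), while its paralog CCNE2 rose 4.67-fold. The median log2 fold change of the list was 0.65 (camera adjusted p = 8.76e-05; adjusted p = 0.802 with an estimated correlation). WT replicate 1 stood apart from the other WT libraries in the same direction, with 24 of these 25 genes higher and a median difference of 0.48. Without that library the median was 0.85.

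Of 25 genes of G2 and mitosis, 17 rose, FOXM1 fell and 7 did not pass, again with the same counts adjusted over the list alone. The kinetochore motor gene CENPE rose from 70.9 ± 5.67 to 196 ± 5.06 CPM, and the spindle kinesins KIF20A and KIF11 rose 1.98-fold and 1.89-fold. The median of the list was 0.40 (camera adjusted p = 2.28e-04; adjusted p = 0.802 with an estimated correlation). All 12 measured replication-dependent histone genes rose, also when adjusted over the list alone, by 0.88 to 2.17 on the log2 scale. H1-2 went from 10.4 ± 0.717 to 23.1 ± 2.56 CPM and H1-4 from 0.485 ± 0.0306 to 1.99 ± 0.0954 CPM (SD, n = 3). The median of the histone list was 1.64 (camera adjusted p = 8.76e-05; adjusted p = 0.802 with an estimated correlation). Most histone transcripts lack a poly(A) tail, so their counts after oligo(dT) selection cover a part of the pool.

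Most members of the Hippo and YAP list, which holds components of the Hippo pathway and targets of its effector YAP, fell. Of 25 measured members, 20 fell, LATS1 and AJUBA rose and 3 did not pass, with the same counts adjusted over the list alone. The matricellular genes CCN2 and CCN1 fell from 1144 ± 259 to 236 ± 12.7 CPM and from 2972 ± 625 to 795 ± 19.3 CPM (SD, n = 3), and the phosphatase gene PTPN14 fell by 1.38 on the log2 scale. The median was -0.60 (camera adjusted p = 2.28e-04; adjusted p = 0.802 with an estimated correlation). WT replicate 1 stood apart from the other WT libraries in the direction of KO here too, with 7 of the 25 genes higher and a median difference of -0.22, and CCN2 at 854 CPM against 1350 and 1228 CPM.

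Genes of cholesterol and fatty acid synthesis also fell as a list. Of 28 members, 18 fell, PMVK, SREBF1, FADS1 and FADS2 rose and 6 did not pass, with the same counts adjusted over the list alone. HMGCS1, which makes HMG-CoA for the mevalonate pathway, fell from 334 ± 42.9 to 65.1 ± 10.7 CPM (SD, n = 3). ELOVL6, which elongates fatty acids, fell by 1.48 on the log2 scale, and the sterol desaturase gene SC5D by 1.73. The median was -0.61 (camera adjusted p = 0.00629; adjusted p = 0.802 with an estimated correlation).

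In the mesenchymal list 13 of 20 measured members fell, VIM, SNAI2, TGFBI and S100A4 rose and 3 did not pass; adjusted over the list alone 14 fell and 4 rose. TAGLN, an actin-binding protein gene, fell from 23.2 ± 0.713 to 2.01 ± 0.374 CPM and the matrix gene TNC from 124 ± 1.46 to 41.4 ± 1.15 CPM, while LOX, a collagen crosslinking oxidase, fell from 301 ± 54.1 to 55.2 ± 5.50 CPM (SD, n = 3). The median was -0.54 (camera adjusted p = 0.0308; adjusted p = 0.802 with an estimated correlation). Without KO replicate 3 the camera adjusted p of the mesenchymal list was 0.0719. In WT replicate 1, 5 of the 20 genes were higher than in the other WT libraries, with a median difference of -0.12.

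**Figure D2:**
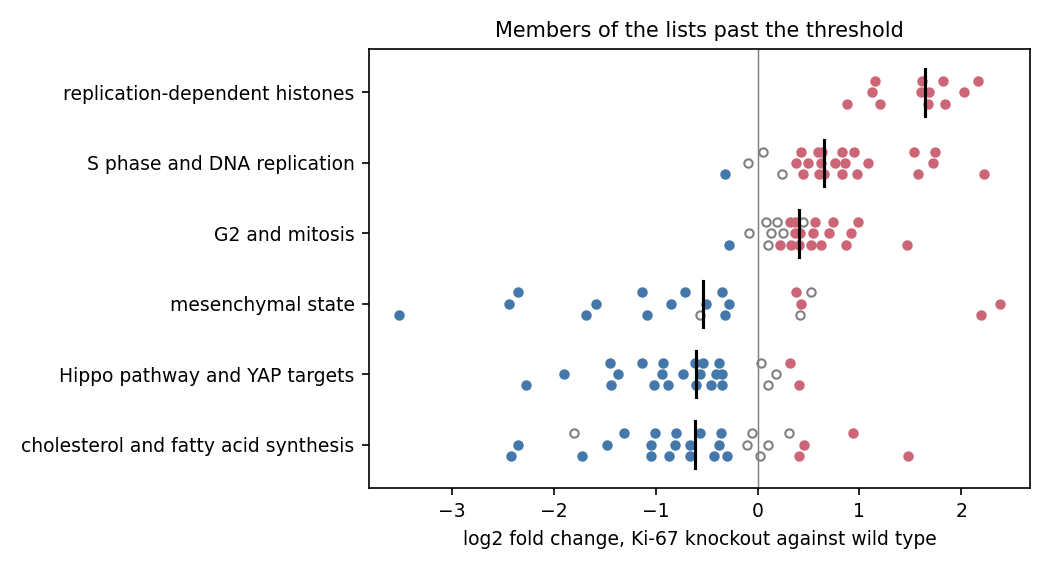
Log2 fold change of each measured member (horizontal axis) of the 6 gene lists past the camera threshold. Filled points passed the edgeR test (red higher, blue lower in knockout), open points did not, and black lines are list medians, from 1.64 for histones to -0.61 for cholesterol and fatty acid synthesis; none of the 6 lists passed with an estimated correlation.

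The other 24 tested lists did not pass the camera threshold (adjusted p from 0.0599 to 0.986), although many of their members changed. In the inflammatory and NF-kB list 14 of 23 genes fell and IL11, TNFAIP2 and NFKB1 rose (median -0.66, camera adjusted p = 0.0599). IL11 rose 4.81-fold, and the chemokine gene CXCL8 fell from 88.3 ± 11.1 to 11.2 ± 2.80 CPM (SD, n = 3). WT replicate 1 lay in the direction of KO in this list as well, with 4 of 23 genes higher than in the other WT libraries and a median difference of -0.19. Relative to its neighbours TNFAIP2 rose by 0.83 rather than 1.46 on the log2 scale. The inflammatory list passed without WT replicate 1 (camera adjusted p = 0.0374), without KO replicate 1 (0.0292), with library size alone (0.0457) and with no filter on low counts (0.0202). It did not pass with an estimated correlation (camera adjusted p = 0.802) or when any other library was left out. Of 24 growth factor and receptor genes 14 fell, among them the EGFR ligand genes EREG (log2 fold change -3.56) and AREG (-1.97), and MET, IGFBP4, IGFBP6 and NRG1 rose (median -0.43, camera adjusted p = 0.0987, and 0.0360 with no filter on low counts; adjusted p = 0.802 with an estimated correlation). Members named where 5 or fewer moved one way were chosen after their values were seen.

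Epithelial genes went both ways, with CLDN4, CLDN7, TJP3, KRT19 and XBP1 lower and KRT18, KRT7, ELF3 and GATA3 higher of 16 measured (median -0.09). The tight junction gene CLDN4 fell from 47.9 ± 2.92 to 1.31 ± 0.306 CPM (SD, n = 3). Of 24 adhesion and migration genes 8 rose and 9 fell, or 8 and 10 adjusted over the list alone (median -0.06). MCAM, a melanoma-associated adhesion molecule, fell by 5.65 on the log2 scale and the cadherin gene CDH11 rose by 4.17. Of 25 extracellular matrix genes 11 rose and 10 fell, with COL4A5 and LAMA3 higher and LAMA4 lower (median 0.00, mean 0.36). Of 15 mammary stem and basal genes ALDH1A3, SOX9, NOTCH3, NRP1 and CD24 rose and 7 fell, or 6 and 8 adjusted over the list alone. ALDH1A3, a retinaldehyde dehydrogenase gene, rose by 4.23 on the log2 scale, and by 3.27 and 3.32 in the counts of either strand setting. PROCR fell 2.05-fold and MYC fell from 344 ± 76.3 to 99.7 ± 4.47 CPM (SD, n = 3). The median of the stem and basal list was -0.25 and its mean 0.11.

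Nuclear regulators were mixed as well. In the list of Ki-67 partners and heterochromatin genes 12 rose and 6 fell of 23 (median 0.33, camera adjusted p = 0.224, and 0.0459 with no filter on low counts; adjusted p = 0.802 with an estimated correlation), with the histone methyltransferase gene SUV39H2 up 2.39-fold. The Polycomb list holds members of the complexes and also the histone demethylase genes KDM6A and KDM6B. Of its 22 measured genes 12 rose, or 13 adjusted over the list alone, and EZH1, JARID2, PHF1, CBX7 and KDM6B fell. The median was 0.44 (camera adjusted p = 0.110, 0.0202 with no filter on low counts, and 0.802 with an estimated correlation). RBBP7 rose by 1.02 on the log2 scale, 0.39 relative to its neighbouring genes, and CBX8 rose by 1.72. The CDK inhibitor and quiescence list also holds D-type cyclin genes. Of its 16 measured members CDKN2C, RBL1, BTG2 and the cyclin genes CCND1 and CCND3 rose and 7 fell (median -0.21). Adjusted over the list alone, 9 fell. CDKN2C was up 2.07-fold and GAS6 down 1.85-fold. Of 20 p53 targets 8 rose and 6 fell, or 8 and 7 adjusted over the list alone, with BBC3 and GADD45A lower and MDM2 higher (median -0.01, mean 0.01).

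Of 28 phase I xenobiotic genes 16 rose and 9 fell, with ALDH1A3 higher and the dioxin receptor gene AHR lower (median 0.54). Of 25 phase II and transport genes GSTP1, NAT1, ABCC5, ABCG2 and SLCO4A1 rose and 7 fell, with HNMT down 3.03-fold beside UGT8, and the median was 0.10 where the mean was -0.43. In the NRF2 and glutathione list 10 rose and 6 fell of 21 (median 0.13), and GCLM rose from 92.1 ± 1.40 to 262 ± 18.6 CPM (SD, n = 3). Glycolysis and hypoxia genes split 10 and 10 of 27 (median 0.01), with CA12 higher, while BNIP3 fell by 1.42 on the log2 scale, and by 0.78 relative to its neighbours. Of 28 nuclear oxidative phosphorylation genes 7 rose and SDHD, SDHA, NDUFV1, NDUFA9 and NDUFB5 fell (median above 0 and mean below 0, both under 0.01 in size). SDHA fell by 1.38, and by 0.68 relative to its neighbours. Of 22 unfolded protein response and ATF4 targets 7 rose and 9 fell, or 7 and 11 adjusted over the list alone (median -0.36), with SLC7A5 up 2.26-fold and PHGDH down 3.94-fold. TGF-beta and BMP genes gave 11 higher and 6 lower of 22 (median 0.30), with PMEPA1 up 16.7-fold. Wnt genes gave 6 higher and 7 lower of 20 (median -0.01, mean 0.03). DKK3 fell by 1.73 on the log2 scale, and by 0.39 and 0.52 in the counts of either strand setting, where reads of overlapping genes cannot be told apart.

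Interferon response genes split 7 and 7 of 30, or 4 higher and 6 lower adjusted over the list alone, with IRF7 lower and IRF1 higher. The median of the interferon list was 0.16 and its mean 0.52. Of 17 MHC class I genes HLA-E fell 2.13-fold, NLRC5 fell, PSMB10 rose and 14 did not pass (median 0.04); HLA-E alone passed when adjusted over the list alone. Of 7 measured MHC class II genes CD74 and HLA-DMB rose and CTSS fell, or 1 rose and 1 fell adjusted over the list alone (median 0.34). CD74 rose by 1.60 on the log2 scale, by 0.66 and 0.76 in the counts of either strand setting and by 0.85 without KO replicate 1. Without WT replicate 1, 2 or 3 the log2 fold change of PSMB10 was 0.58, 0.56 or 0.57, against 0.58 over all libraries. That of CD74 was 1.60, 1.65 or 1.54, so these changes kept about their size where the call was lost. Without KO replicate 1, PSMB10 rose by only 0.27 and HLA-DMB by 0.82. Calls near the threshold were lost when single libraries were left out, with the following edgeR adjusted p. NLRC5 was not called without WT replicate 2 (0.0720), KO replicate 1 (0.0688) or KO replicate 3 (0.0788). PSMB10 was not called without WT replicate 1 (0.0638), 2 (0.0747) or 3 (0.0792) or KO replicate 1 (0.215). CD74 was not called without WT replicate 1 (0.0753), 2 (0.0569) or 3 (0.0569). HLA-DMB was not called without WT replicate 2 (0.149) or 3 (0.163) or KO replicate 1 (0.191), 2 (0.0571) or 3 (0.0539). HLA-DMB was also not called by DESeq2 (adjusted p = 0.182), PSMB10 by limma-voom (adjusted p = 0.0538), and NLRC5 and PSMB10 in the counts of the second strand setting (edgeR adjusted p = 0.0905 and 0.169).

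Markers of other cell types were few. Of 20 leukocyte markers 3 were measured. CD8A stood at 0.726 ± 0.142 and 1.30 ± 0.287 CPM and PTPRC at 0.503 ± 0.149 and 0.241 ± 0.0807 CPM in WT and KO (SD, n = 3). CD8A was not called without WT replicate 1 (edgeR adjusted p = 0.0570), WT replicate 3 (0.0605) or KO replicate 1 (0.0821), and PTPRC not without WT replicate 1 (0.149), WT replicate 2 (0.0581), KO replicate 1 (0.124) or KO replicate 3 (0.0782). DESeq2 called neither CD8A (adjusted p = 0.0743) nor PTPRC (adjusted p = 0.187). CD8A was also not called in the counts of the first strand setting (edgeR adjusted p = 0.0739), and PTPRC not with no filter on low counts (edgeR adjusted p = 0.0585). Of 6 measured fibroblast and endothelial markers COL1A1 and PECAM1 rose and TIE1, ESAM and RGS5 fell (median 0.12, mean -0.44). ESAM was not called relative to its neighbours (edgeR adjusted p = 0.301), and RGS5 not without WT replicate 2 (0.0617), WT replicate 3 (0.0602) or KO replicate 1 (0.0524) and not in the counts of the second strand setting (0.0620). The 28 cancer-testis genes held 21 counts per WT library and 36 per KO library in all, too few for a test of any of them. Ribosomal protein genes had a median of -0.02, with 6 higher and 8 lower of 30, or 5 and 7 adjusted over the list alone. Of 15 mitochondrially encoded genes MT-ND3, MT-ND5, MT-ND6 and MT-CYB rose and MT-ND1, MT-ND2, MT-ND4, MT-ATP6 and MT-RNR1 fell (median -0.04). In the counts of the second strand setting MT-CYB and MT-ND3 were not called (edgeR adjusted p = 0.284 and 0.248).

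In a minority of chromosome regions neighbouring genes shifted in the same direction. On chromosome 17, 76.1% of 657 expressed genes were higher in KO, with a median log2 fold change of 0.44, and on chromosome 13, 28.5% of 207 were, with a median of -0.34. In 20-Mb blocks, median changes were 0.70 on chromosome 5 from 160 to 180 Mb, 0.64 on chromosome 14 from 100 to 120 Mb, -0.75 on chromosome 5 from 0 to 20 Mb and -0.61 on chromosome 18 from 0 to 20 Mb. The block that holds MKI67, chromosome 10 from 120 to 140 Mb, had a median of -0.66, and -0.64 without MKI67. Other named genes lie in shifted blocks too, so part of their change ran with that of their neighbours. Among them are POLA1 (chromosome X from 20 to 40 Mb, median 0.62), SUV39H2 (chromosome 10 from 0 to 20 Mb, 0.55) and SC5D (chromosome 11 from 120 to 140 Mb, -0.55). Of 152 blocks, 11 had a median of at least 0.4 and 13 of -0.4 or lower, while 109 had a median under 0.2 in size, and a block explained 6.65% of the variance of held-out genes. All 6 lists above stayed past the camera threshold when each gene was taken relative to its neighbours, and none of them passed with an estimated correlation (camera adjusted p = 0.802 for each).

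**Figure D3:**
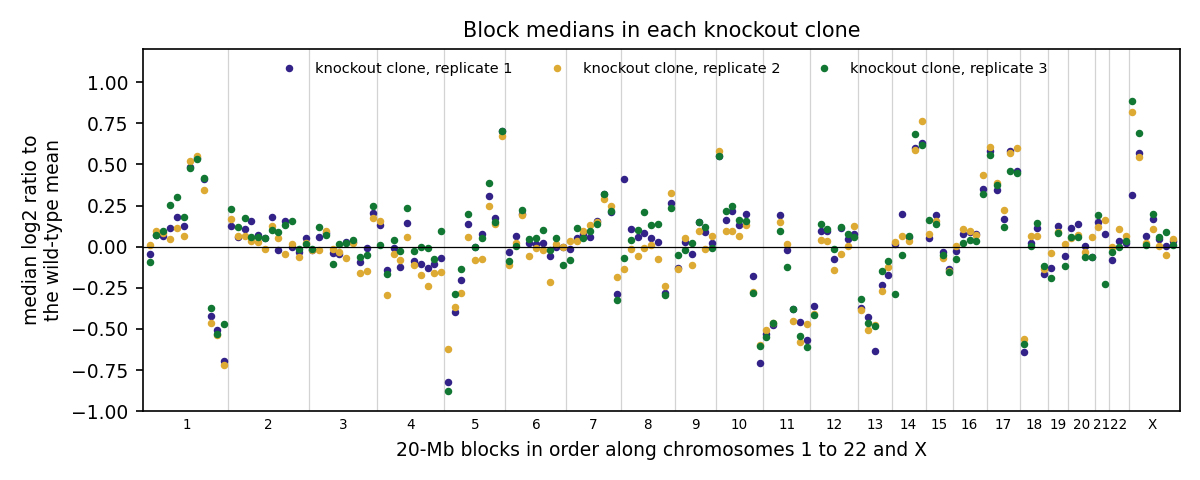
Median log2 ratio of each knockout clone to the wild-type mean (vertical axis) in 152 blocks of 20 Mb in order along the chromosomes (horizontal axis); each color is 1 clone. In most blocks the 3 clones lie close together, and in 4 blocks they are at least 0.3 apart.

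The clones also differed from each other. The biological coefficient of variation was 12.1% among the KO libraries and 9.43% among the WT libraries. Among genes with a mean of at least 2 CPM, 11 were at least 8-fold apart between KO libraries, against 0 between WT libraries. CACNA2D4, a calcium channel subunit gene, was highest in KO replicate 2 and spanned 5.77 on the log2 CPM scale between the clones. GNG2 stood at 5.39, 4.63 and 0.102 CPM in KO replicates 1 to 3 and the transcription factor gene PAX9 at 3.31, 3.01 and 0.0679 CPM, so KO replicate 3 was the low one in both. CCL2, a monocyte chemoattractant gene, was at 59.6, 73.6 and 67.7 CPM in the WT libraries and at 0.292, 7.21 and 1.43 CPM in the clones. These genes were chosen after their values were seen, and each clone had 1 library, so differences between clones were not tested.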

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

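The neighbour-relative changes and the same genes without centring were added after the data had been seen; the other alternatives were planned. The number of changed genes, 9580, lay between 8225 and 9908 when 1 library was left out, at 9123 with DESeq2 and at 9594 with limma-voom, and stayed within 1.5 times under every alternative run. For MKI67 the log2 fold change was -2.93 to -2.65 when 1 library was left out. Genes of at least 2-fold fell to 1526 with glmTreat, which tests against that fold itself. The lists past the threshold numbered 5 to 7 when 1 library was left out, 10 with no filter on low counts, where 34216 genes formed the background, 0 with an estimated correlation, 18 with fry and 10 with fry and the replicate block, where the S phase list was lost (fry adjusted p = 0.0679). Fry asks another question than camera; the cause of the other shifts was not tested. Replicate numbers did not pair the libraries (correlations of deviations -0.004, -0.031 and 0.023), and not every library went best with its own number. The replicate block gave 9357 genes and 5 lists, without the mesenchymal list (camera adjusted p = 0.0601), and ended the call of PTPRC (edgeR adjusted p = 0.0577). Relative to neighbouring genes 9160 genes were called, against 9463 of the same 15941 genes without centring, and 7991 of the 9580 were called again, 77 of them with the other sign. SDHC turned from 0.48 to -0.0683 there (edgeR adjusted p = 0.448), and NPM1, HLA-DMB, ESAM, RPLP2 and RPS27 were no longer called. Over all alternatives, genes named by the rule kept direction and call in 2425 comparisons, lost the call in 42 and reversed in 1. At these depths a gene with 0 counts over a group allows only a bound on the fold, and a gene near 3 counts only a wide counting interval.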

Other observations

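The shuffling, GC and length, copy number, histone and mixing tests below were chosen after the result they bear on had been seen at least in part; the block test of WT replicate 1 and the splits of the libraries were written before.

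Small nuclear and nucleolar RNA genes, which are not in any list above, did not follow the histones. Of 35 measured genes 3 rose and 11 fell, with a median log2 fold change of -0.34 and a 95% bootstrap interval of -0.63 to 0.02. In KO replicate 1, genes of chromosome 8 from 0 to 20 Mb had a median of 0.41, against -0.14 and -0.07 in the other clones, and genes of chromosome X from 0 to 20 Mb 0.31 against 0.82 and 0.88. In KO replicate 3, genes of chromosome 14 from 20 to 40 Mb had a median of -0.29 against 0.02 and 0.03, and those of chromosome 21 from 40 to 60 Mb -0.23 against 0.08 and 0.16.

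Neighbouring genes shifted together. The SD of block medians was 0.258, against 0.0906 on average when 10900 genes were shuffled over positions (permutation test with 10000 shuffles, p = 1e-04, the smallest it can give), and blocks of 10 and 40 Mb gave 0.272 and 0.260, which argues against chance placement. A trend on GC content and transcript length left 100% of the SD, but it moved only 3.33% of genes by at least 0.1, under the 5% required for that test. The block medians of the trend itself had an SD of 0.0176 and correlated at -0.105 with those of the change. The fitted trend was thus small beside the block shifts. With the required share of genes not reached, the test cannot decide on bias from GC or length. Clone and WT pairs that share no library gave block medians correlated at 0.873 to 0.935, and held-out genes, in 3 equal classes of expression, followed their block in the lowest class with 0.902 (SE 0.0960) times the slope of the highest, as a difference in DNA copy number carried by all 3 clones would give. Copy number is therefore a candidate explanation, as a hypothesis, but no DNA was analysed, and regional regulation after Ki-67 loss was not tested.

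Replication-dependent histone genes rose together. More carry-over of RNA without a poly(A) tail would raise small nuclear and nucleolar RNA too, but their median was -0.336. Per-gene counts cannot tell whether reads in these genes come from longer transcripts around them, and reads outside annotated features also fell in KO. Carry-over therefore stays open. The histone list median of 1.59 relative to neighbouring genes argues against a shift of the chromosome block of the histone genes. A larger share of cells in S phase may account for part of the histone rise, since the S phase list rose with a median of 0.652. That is less than the 1.64 of the histones, and the call of the S phase list is lost with an estimated correlation (camera adjusted p = 0.802). In WT replicate 1 the S phase list stood a median of 0.478 above the other WT libraries, with 24 of 25 genes higher. The histone list stood only 0.146 above them there, with 8 of 12 genes higher, against 1.52 in KO. Those values rest on a single WT library. The share of cells in each phase was not measured, and an effect of Ki-67 loss on histone transcripts themselves was not tested.

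WT replicate 1 lay 11.5% of the way from the other WT libraries to KO on the first principal component. Knockout cells mixed into it would bring transcripts that WT cells lack, but 12 genes near silent in WT replicate 2 stood at 1.90% (1.27% to 2.72%) of their KO level there and at 1.77% (1.15% to 2.62%) in WT replicate 3. The shift of WT replicate 1 would need a median of 12.7% of KO RNA (12.1% to 13.3%) over 9568 other changed genes and 36.0% (21.2% to 41.5%) over 22 changed S phase genes, so mixing is argued against. For a subline that carries part of the chromosome blocks, a correlation over 0.5 between the block shifts of WT replicate 1 and of KO, in separate genes, was set beforehand, and under 0.2 for none; it was 0.179, and its 95% interval of 0.0209 to 0.329, added after the correlation had been seen, lies below 0.5 and spans 0.2, so a subline with few of the blocks stays open. The state of the culture at harvest could also move S phase genes, and was not tested.

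Of the 10 ways to split the 6 libraries into groups of 3, 1, the real one, gave as many changed genes by edgeR, 9580, and the highest of the others gave 0, with 31 to 248 genes at an unadjusted p under 0.05 and 0 by limma-voom. With 10 splits no share under 0.05 is possible. Each of the other splits also placed WT and KO libraries in both groups. The difference between WT and KO then raised the spread within groups, so few calls could arise there. The splits therefore cannot test the calls.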
